A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

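Total RNA from 4 FD11 and 4 reference samples was labelled with Cy3 and hybridised to one-colour Agilent yeast arrays, one array per sample, per the labels' protocols. The design text speaks of triplicate cultures, while 4 arrays per strain were deposited, and the source name of reference replicate 4 carries the number of replicate 3. Samples were grouped by their titles.

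The scanner files hold spot intensity values, deposited by the authors as Feature Extraction wrote them. The software is version 10.7.3.1 per the file headers and version 9.1 per the submitters' processing notes. The processed intensity is background-subtracted and detrended but not normalized between arrays, per the file headers. The authors also deposited a value table in log2 units, with 6316 rows. Its columns have nearly equal medians, 10.37, 10.37, 10.35 and 10.36 for FD11 replicates 1 to 4 and 10.37, 10.37, 10.37 and 10.36 for the reference, and follow the log2 of the uncorrected spot median. The table was therefore used only as an alternative, and how it was normalized is not given in the sources used here. Its column maxima were also equal, at 18.62, except for 18.58 in FD11 replicate 4. As an alternative it may therefore not be independent of the quantile normalization tried below. No column of it was left unassigned (0 columns).

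Each array carries 6256 gene probes in 2 spots. The log2 processed signal of each spot was set relative to the array's 75th percentile over gene spots, which lay between 2444 and 5049 units. Spots marked as non-uniform or population outliers, at most 15 on an array, were left out and the spots of a probe averaged. Each systematic name had 1 probe. Names were updated through a table of the S288C assembly R64, in which 5756 of 6256 systematic names matched; the others keep the array's name. The table was used for names and chromosomes only, since the array design rests on another build.

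Genes were tested if well above background on at least 3 of 4 arrays of either strain, which kept 5938 and left out 318. Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over genes, threshold 0.05). Where a strain had no array well above background, a fold is a bound. It sets the brighter strain's mean against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. Using bounds moved no list median by more than 0.28.

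Gene lists (51) and chromosomes (16) were tested with camera at a preset correlation of 0.01, with at least 4 tested members. Camera with an estimated correlation and fry were alternatives. Genes were named by a rule set before the data were examined. It takes the 12 largest increases and decreases with adjusted p under 0.05, all arrays of one strain on one side of the other's, and signal well above background on at least 3 arrays of each strain. It adds the 3 largest changes that fail only the last condition, and up to 3 called members with the largest change from each list that was called or holds 3 or more called members. Genes of the a-specific and alpha-specific lists may be named as a check of the strain.

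Other choices tried were quantile normalization, median scaling, normexp (offset 50), no or a stricter detection filter, an intensity trend with robust variance, array weights, the replicate number as a block, the slide as a random block, the authors' table, replicates 1 to 3 alone, reference replicates 3 and 4 averaged, and each array left out. Normexp used the spot median in place of the spot mean, which the files used here lack.

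The fit was tested on simulated data with the real arrays' means and spread, over 5938 genes. Of 50 genes changed by 0.3, 0.6, 1 or 2 on the log2 scale, 16%, 76%, 94% and 98% were called, with 5 calls among 5738 unchanged genes. A chromosome III shifted by 1 was called (adjusted p = 1.99e-07) with 0 of the 15 others. Simulated genes were drawn independently of each other and without a slide effect. These rates therefore do not cover genes that vary together or a difference between slides.

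Arrays of a strain correlated across genes between 0.993 and 0.997, and no pair shared identical values (0 genes). Reference replicates 3 and 4 differed by a median of 0.10 on the log2 scale, and replicates 1 and 2, also of one slide, by 0.12.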

Results

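Messenger RNA levels were measured in FD11, a Saccharomyces cerevisiae strain that the series describes as propolis-resistant and obtained by evolutionary engineering, and in its reference strain, a laboratory strain of the CEN.PK family. Propolis is a resinous bee product. Both strains grew without treatment in minimal medium with 2% glucose at 30 °C and 150 rpm, from an OD600 of 0.1, and were harvested in exponential phase at an OD600 of about 1.0. One-colour Agilent arrays were deposited for 4 FD11 and 4 reference samples, each with 6256 gene probes in 2 spots. Between 92.9% and 95.3% of gene spots lay well above background on each array, and no gene spot was saturated. The number of arrays limits the precision of the values below. The design text speaks of triplicate cultures, but the labels do not say that the 4 arrays of a strain came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. All differences below are FD11 minus reference on the log2 scale, relative to each array's 75th percentile.

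The comparison asks which transcripts differ between the resistant strain and its reference in untreated cultures. General stress, heat shock, and trehalose and glycogen transcripts were higher in FD11, with list medians of 3.17, 2.20 and 1.97, and ribosome biogenesis transcripts were lower, with a median of -2.67. These calls by camera did not hold with an estimated correlation (adjusted p = 0.456 for each list). Of 5938 genes tested, 2515 were higher and 2332 lower in FD11 at an adjusted p under 0.05 (limma). The difference was at least 2-fold for 1092 of the higher and 943 of the lower genes. Genes had a median SD of 0.14 among FD11 arrays and 0.11 among reference arrays, while the SD of the strain differences over genes was 1.28. Every FD11 array came from one slide, scanned in another year and at another resolution than the 2 slides of the reference. By this design the time of the experiment or scan and the strain cannot be told apart in any difference given here. For the gap between general stress and ribosome biogenesis genes alone, spike-in RNAs argue against the scan, as given below.

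The 12 largest increases with signal in both strains were led by TMA10 (YLR327C), 134-fold higher, at 5.25 ± 0.18 in FD11 against -1.82 ± 0.45 in the reference (SD, n = 4 each). BDH2 (YAL061W), related to butanediol dehydrogenase, was higher by 6.79 ± 0.11 (SE). HXK1 (YFR053C), a hexokinase, was higher by 6.63 ± 0.20. CYC7 (YEL039C), an isoform of cytochrome c, was higher by 6.60 ± 0.20. RGI1 (YER067W) was higher by 6.37, CIS1 (YLR346C) by 6.29 and EGO4 (YNR034W-A) by 5.90. The glycogen phosphorylase gene GPH1 (YPR160W) was higher by 6.03, the small heat shock protein gene HSP26 (YBR072W) by 5.74 and the phosphoglucomutase gene PGM2 (YMR105C) by 5.33. The high-affinity glucose transporter genes HXT7 (YDR342C) and HXT6 (YDR343C) were higher by 5.28 and 5.24, but their sequences are nearly identical and their probes may not separate them. Adjusted p-values of these 12 genes ranged up to 1.97e-09. RSB1 (YOR049C), which encodes a transporter of sphingoid bases, was not well above background on any reference array and was at least 205-fold higher in FD11 (adjusted p = 1.44e-10). YMR206W was likewise at least 61.6-fold higher (adjusted p = 5.91e-10).

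Among the 12 largest decreases, PHO84 (YML123C), the high-affinity phosphate transporter, was 91.3-fold lower, at -7.04 ± 0.09 in FD11 against -0.53 ± 0.17 in the reference (SD, n = 4 each). DBP2 (YNL112W), an RNA helicase, fell by 5.73 ± 0.08 (SE). AAH1 (YNL141W), adenine deaminase, fell by 5.14 ± 0.14. ZRT1 (YGL255W), the high-affinity zinc transporter, fell by 5.03 ± 0.32 and varied more between FD11 arrays (SD 0.82). NSR1 (YGR159C), a nucleolar protein gene, fell by 4.90, ALB1 (YJL122W) fell by 4.23, DHR2 (YKL078W) fell by 4.18, SDA1 (YGR245C) fell by 4.05 and RSA4 (YCR072C) fell by 3.95. AQR1 (YNL065W), a plasma membrane exporter, fell by 4.02. ERG20 (YJL167W), farnesyl pyrophosphate synthase, fell by 3.99 and GFD2 (YCL036W) fell by 3.94. The highest adjusted p of the 12 was 5.39e-08, for ZRT1. ARO3 (YDR035W), an enzyme of aromatic amino acid synthesis, was also lower in FD11 (adjusted p = 1.36e-09), but was well above background there on only 1 of 4 arrays, so no size is given.

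Of 51 gene lists fixed before the data were examined, 18 were called by camera with a preset correlation, 14 higher and 4 lower in FD11. None of the 18 held with an estimated correlation, whose adjusted p is given beside each. The adjustment over lists gave many of them the same value, 0.456. Before adjustment, camera p with an estimated correlation ran from 0.00622 for the targets of Pdr1 and Pdr3 to 0.423 for the respiratory chain and ATP synthase. The counts of called members were the same adjusted over the list alone, except for 3 lists named with theirs.

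Most targets of Pdr1 and Pdr3, transcription factors of multidrug resistance, were higher in FD11. Of 19 members tested, 17 were higher and 1 lower, with a median difference of 1.5 (1.49 with its 2 bounded members at their bounds; camera, adjusted p = 2.14e-05, and adjusted p = 0.317 with an estimated correlation). Besides RSB1 and CIS1, the drug efflux pump gene PDR5 rose by 3.58 ± 0.13 (SE), from -0.91 ± 0.29 to 2.67 ± 0.08 (SD, n = 4 each, limma, adjusted p = 6.43e-10). TPO1, a polyamine exporter gene, was the member that fell, by 0.31 (adjusted p = 0.00995), and IPT1 did not pass the test, at -0.14 (adjusted p = 0.184). TPO1 and IPT1 were chosen after their values were seen. The list of drug and weak acid exporters, which shares 6 tested genes with the regulon, did not move as a whole: 8 of 22 were higher and 11 lower (adjusted p = 0.576). Its members with the largest differences were AQR1, PDR5 and the efflux pump gene SNQ2, which rose by 2.98.

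**Figure D1:**
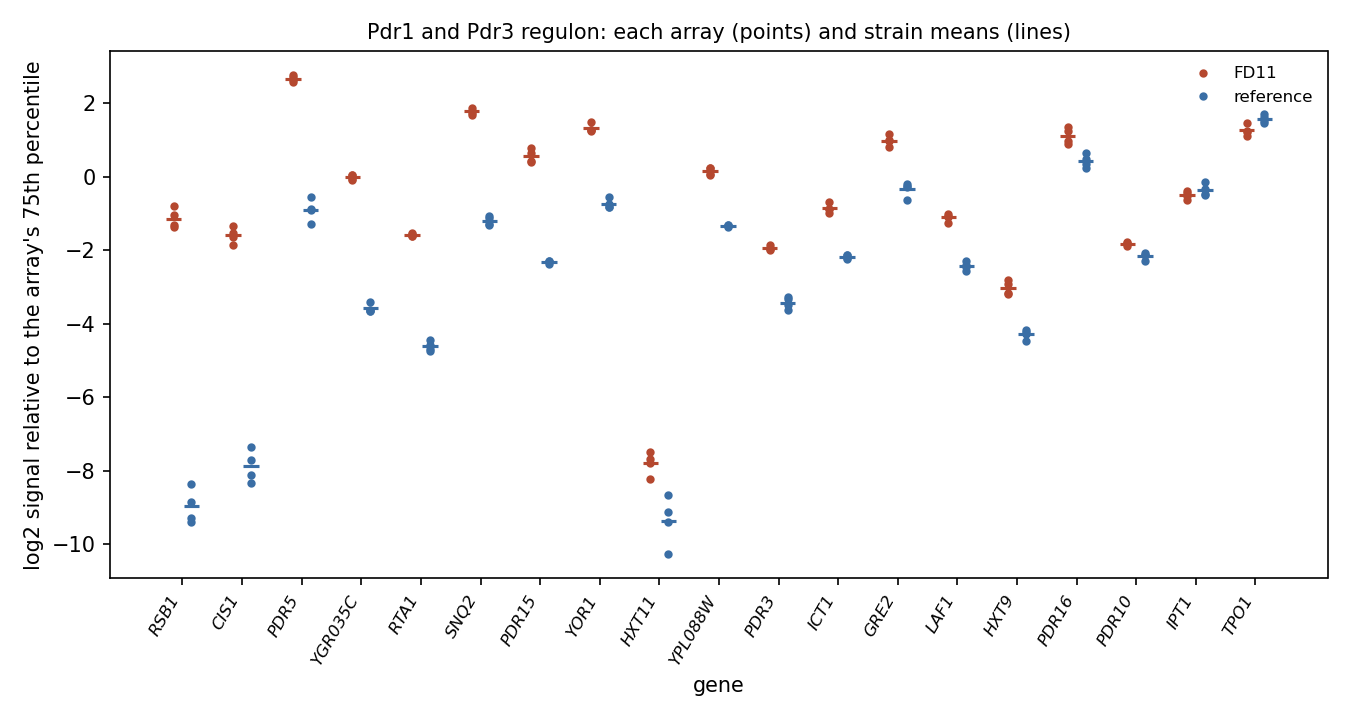
Log2 signal relative to the array's 75th percentile (vertical axis) of the 19 tested genes of the Pdr1 and Pdr3 list (horizontal axis, ordered by difference), with a point per array, 4 for each strain, and a line at each strain's mean. FD11 lies above the reference for 17 genes passing the test, while IPT1 and TPO1 lie at differences of -0.14 and -0.31.

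Stress genes were higher over a wide front. All 38 tested genes of the general stress list rose, with a median of 3.17 (camera, adjusted p = 1.2e-12, and adjusted p = 0.456 with an estimated correlation); HXK1, CYC7 and GPH1 led it. In the heat shock and chaperone list 20 of 23 rose and 1 fell, with a median of 2.20 (adjusted p = 1.31e-05, and adjusted p = 0.456 with an estimated correlation). There BTN2 rose by 4.21 and SSA4, an Hsp70 chaperone gene, by 3.95. Of 30 oxidative stress genes, 23 rose and 1 fell, with a median of 1.04 (adjusted p = 0.000231, and adjusted p = 0.456 with an estimated correlation). Its largest differences were in the catalase gene CTT1 (3.30), the thioredoxin gene TRX2 (3.10) and the glutaredoxin gene GRX1 (2.83). Of 15 osmotic stress genes, 13 rose and 1 fell, with a median of 1.34 (adjusted p = 0.00112, and adjusted p = 0.567 with an estimated correlation), led by HSP12 (5.19), ALD3 (3.86) and GCY1 (3.38). The general stress list shares 5 tested members with the osmotic list, 6 with that of trehalose and glycogen, 2 with that of heat shock, 2 with that of glycolysis and fermentation (HXK1 and GLK1), 1 with that of hexose transporters and 1 with that of oxidative stress.

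Ribosome genes were lower. All 63 tested ribosome biogenesis genes fell, with a median of -2.67 (camera, adjusted p = 7.13e-21, and adjusted p = 0.456 with an estimated correlation); DBP2, NSR1 and MAK16 (-3.91) led it. Of 138 members of the cytosolic ribosomal protein list, 91 fell and 12 rose, with a median of -0.64 (adjusted p = 5.32e-07, and adjusted p = 0.59 with an estimated correlation). The list's name pattern took in RPP1, a subunit of RNase P, and without it 90 of 137 fell and 12 rose (adjusted p = 7.01e-07, and adjusted p = 0.59 with an estimated correlation). RPS11A fell by 2.13, RPS28B fell by 2.03 and RPS4B fell by 2.01, though close paralogs may share signal. Mitochondrial ribosomal protein genes went both ways, with 16 of 56 higher and 27 lower and a median of -0.12 (adjusted p = 0.228); MRPS9 fell by 1.63 and MRP35 rose by 1.49.

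**Figure D2:**
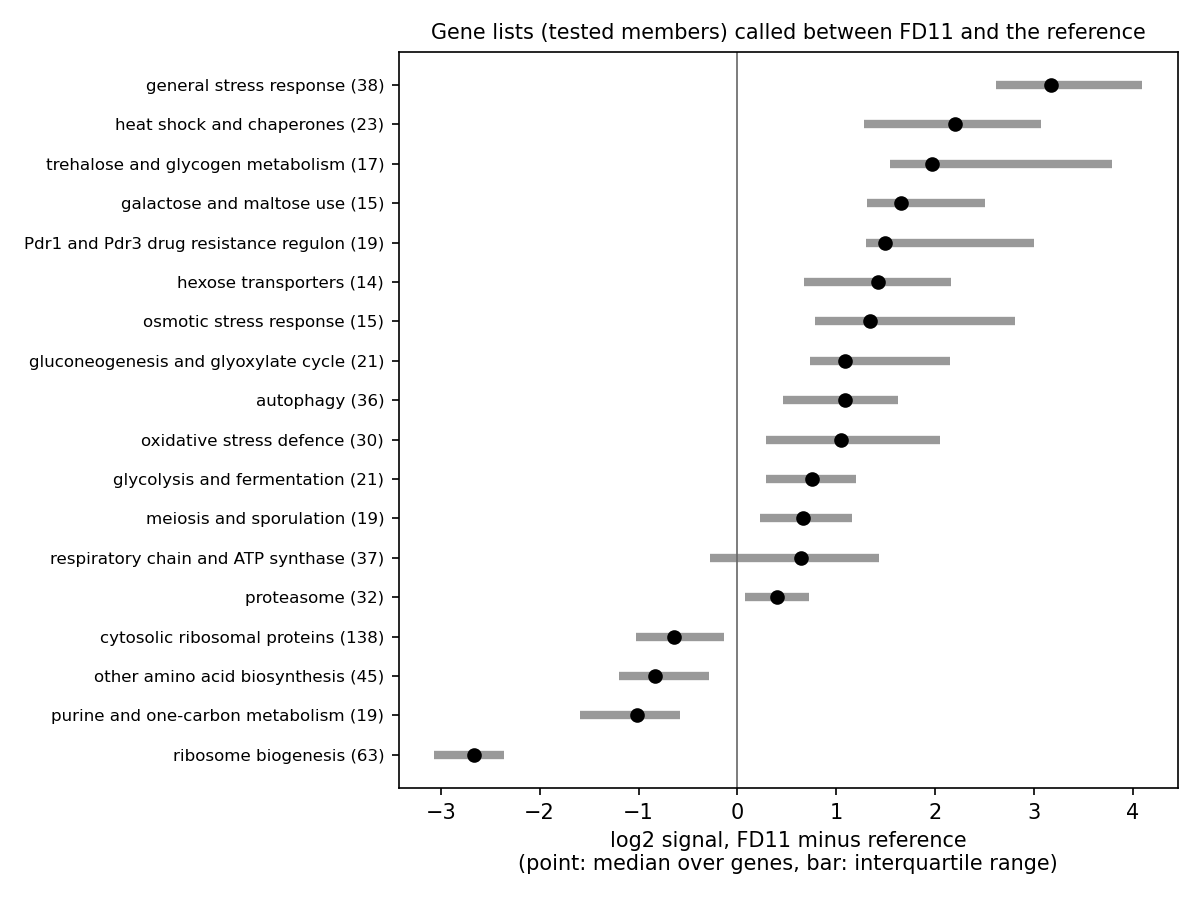
Median log2 difference, FD11 minus reference (horizontal axis), of the 18 gene lists called, with the number of tested members after each name. Points are medians over genes and bars run from the first to the third quartile, from a median of -2.67 for ribosome biogenesis to 3.17 for the general stress response.

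Sugar uptake and storage genes were higher. Of 17 trehalose and glycogen genes, 16 rose and 1 fell, with a median of 1.97 (camera, adjusted p = 1.73e-05, and adjusted p = 0.456 with an estimated correlation). GPH1 and PGM2 led this list, and TSL1, a subunit of trehalose synthase, rose by 4.77. Of 14 hexose transporter genes, 11 rose and 2 fell, with a median of 1.42 (adjusted p = 0.00927, and adjusted p = 0.567 with an estimated correlation); HXT2 followed HXT7 and HXT6, at 3.60. This median was 1.14 with 1 member at its bound, and 0.67 in the authors' value table and 0.86 with normexp, where the list was still called. The hexose transporter list shares 2 tested members with the Pdr1 and Pdr3 list and 1 with that of galactose and maltose. Of 15 galactose and maltose genes, 12 rose and 2 fell, with a median of 1.65 (adjusted p = 0.00275, and adjusted p = 0.456 with an estimated correlation). MAL12 rose by 4.26 and MAL32 by 4.0, a near-identical pair of maltase genes, and the maltose permease gene MAL11 rose by 3.90. Of 21 genes of glycolysis and fermentation, 16 rose and 1 fell, with a median of 0.75 (adjusted p = 0.0103, and adjusted p = 0.59 with an estimated correlation). The glucokinase gene GLK1 rose by 2.58 beside HXK1, and the pyruvate decarboxylase gene PDC5 fell by 3.02. The glycolysis call was lost under quantile normalization (median 0.35, adjusted p = 0.0829) and with the authors' value table (median 0.41, adjusted p = 0.0538), over a range of adjusted p from 0.00558 to 0.0829.

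Genes of growth on non-fermentable carbon were partly higher. In the list of gluconeogenesis and the glyoxylate cycle 19 of 21 rose and 1 fell, with a median of 1.09 (camera, adjusted p = 0.000194, and adjusted p = 0.473 with an estimated correlation). ALD4, a mitochondrial aldehyde dehydrogenase gene, rose by 4.30, CRC1 by 2.56 and SIP4, a transcription factor gene, by 2.51. Respiratory chain and ATP synthase genes rose for 24 of 37 and fell for 11, with a median of 0.64 (adjusted p = 0.0442, and adjusted p = 0.671 with an estimated correlation). COX5B rose by 3.75, STF1 by 3.39 and COX7 by 2.73. This call was lost without FD11 replicate 1 (adjusted p = 0.0522), FD11 replicate 4 (0.0534), reference replicate 1 (0.0557) or reference replicate 2 (0.0561), with no detection filter (0.0503), with array weights (0.0605), with replicates 1 to 3 alone (0.0606), and against reference replicates 3 and 4 alone (0.0735). The list's median was 0.45 against reference replicates 3 and 4 alone, and between 0.55 and 0.65 in the other settings that ended the call. Over 22 alternatives its median ranged from 0.45 to 0.84 and its adjusted p from 0.0157 to 0.0735. The tricarboxylic acid cycle list was not called (adjusted p = 0.24), with 9 of 16 higher and 4 lower; SDH1 rose by 1.86. Peroxisomal fatty acid oxidation was not called either (adjusted p = 0.262), with 7 of 14 higher and 3 lower; SPS19 rose by 1.76. Of 8 mitochondrially encoded genes 6 were higher and 1 lower (adjusted p = 0.227): COX1 rose by 2.73 and COB by 2.05, and VAR1 fell by 1.80. All 3 were higher on the slide of reference replicates 3 and 4 than on that of replicates 1 and 2, and VAR1 was at -1.13 against the latter and at -2.47 against the former.

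Biosynthetic genes were lower in 2 lists. All 19 purine and one-carbon genes fell, with a median of -1.02 (camera, adjusted p = 1.73e-05, and adjusted p = 0.456 with an estimated correlation); of the IMP dehydrogenase genes, IMD4 fell by 3.53, IMD2 fell by 2.37 and IMD3 fell by 1.88. Of 45 other amino acid biosynthesis genes, 36 fell and 5 rose, with a median of -0.83 (adjusted p = 3.87e-05, and adjusted p = 0.456 with an estimated correlation). LEU9 fell by 2.42 and ILV5 fell by 2.37. Lists not called were sulfur and methionine metabolism (4 of 24 higher, 12 lower, adjusted p = 0.103), arginine and ornithine metabolism (3 of 11 higher, 8 lower, adjusted p = 0.349), amino acid permeases (6 of 17 higher, 9 lower, adjusted p = 0.228), nitrogen catabolite repressed genes (10 of 23 higher, 8 lower, median -0.11 but mean 0.23, adjusted p = 0.84) and thiamine and pyridoxine metabolism (9 of 19 higher, 9 lower, median -0.071 but mean 0.016, adjusted p = 0.984). Within them SAM3 fell by 3.46, the methionine permease gene MUP1 fell by 2.85 and the arginase gene CAR1 rose by 2.98. Phenolic acid and aromatic alcohol genes were not called (11 of 17 higher, 4 lower, adjusted p = 0.216), where ARO10 rose by 2.53 and OYE3 by 2.51.

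Nutrient and metal transport genes had large single differences, but none of their lists was called. In the phosphate regulon 4 of 16 were higher and 9 lower (camera, adjusted p = 0.0797): after PHO84, PHM6 fell by 2.95, and PHM8 rose by 2.64. Of 25 iron regulon genes 8 were higher and 14 lower (adjusted p = 0.191). The biotin transporter gene VHT1 fell by 2.86, and the iron permease gene FTR1 and its ferroxidase gene FET3 fell by 2.52 and fell by 2.21. Of 17 copper and zinc genes 4 were higher and 11 lower (adjusted p = 0.0594), with ZRT1 down and the metallothionein genes CUP1-1 and CUP1-2, which are near-identical copies, up by 3.82 and 3.73.

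Protein turnover genes were higher. Of 36 autophagy genes 31 rose and 2 fell, with a median of 1.09 (camera, adjusted p = 9.4e-06, and adjusted p = 0.456 with an estimated correlation); ATG8 rose by 2.75 and ATG17 by 2.71. Of 32 proteasome genes 22 rose and 2 fell, with a median of 0.40 (adjusted p = 0.0123, and adjusted p = 0.456 with an estimated correlation), led by RPN8 at 1.55. Vacuolar ATPase genes were not called (2 of 13 higher, 7 lower, adjusted p = 0.549), nor was the unfolded protein response (7 of 14 higher, 3 lower, adjusted p = 0.502), where the chaperone gene KAR2 rose by 1.37.

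Cell surface and lipid lists were not called. Cell wall integrity targets were higher for 14 of 23 and lower for 6 (camera, adjusted p = 0.0797), and SED1 rose by 2.41. Cell wall structure and remodelling had 5 of 29 higher and 16 lower (adjusted p = 0.0843), and TIR2 fell by 2.23. Daughter cell separation had 3 of 11 higher and 5 lower (adjusted p = 0.549), and flocculins and adhesins 2 of 8 higher and 3 lower (adjusted p = 0.926), with FLO11 up by 2.15. The flocculin median was 0.15, while the test, relative to other genes, pointed down. Seripauperins and anaerobic mannoproteins had 19 of 30 higher and 5 lower (adjusted p = 0.0797), and calcineurin and calcium genes 9 of 12 higher and 1 lower (adjusted p = 0.103). Ergosterol synthesis had 6 of 27 higher and 14 lower (adjusted p = 0.218), with ERG20 down and ERG28 up by 1.64. Fatty acid and sphingolipid synthesis had 9 of 24 higher and 11 lower (adjusted p = 0.576), and AUR1 fell by 2.06. Phospholipid synthesis had 7 of 14 higher and 5 lower (adjusted p = 0.618), and INO1, inositol phosphate synthase, rose by 3.50.

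Cell cycle lists were not called. Replication and G1 to S genes were higher for 6 of 28 and lower for 15 (camera, adjusted p = 0.137), and the G1 cyclin genes CLN2 and CLN1 fell by 2.19 and fell by 1.74. G2 to M genes were higher for 2 of 15 and lower for 9 (adjusted p = 0.0884), and CLB1 fell by 2.32. Histones had 2 of 10 higher, or 1 adjusted over the list alone, and 3 lower (adjusted p = 0.809). DNA damage genes had 9 of 13 higher and 2 lower (adjusted p = 0.0594), and PHR1 rose by 2.54. The meiosis and sporulation list was called, with 13 of 19 higher, or 12 adjusted over the list alone, 2 lower and a median of 0.66 (adjusted p = 0.0339, and adjusted p = 0.584 with an estimated correlation). Its member MEK1 was not well above background on any reference array and was at least 2.70-fold higher (adjusted p = 4.96e-07). The call was lost with quantile normalization (adjusted p = 0.254), normexp (0.103), an intensity trend (0.0614), the authors' value table (0.289), and the reference slide with replicates 3 and 4 alone (0.0569). Its median ranged from 0.22 with the authors' values to 0.76 and its adjusted p from 0.0186 to 0.289.

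Mating genes were examined as a check of the strain, and none of their lists was called. Of 7 a-specific genes 3 were higher and 2 lower, with a median of 0.21 but a mean of -0.031 (camera, adjusted p = 0.875); STE2, the alpha-factor receptor gene, fell by 1.78 and stayed well above background on all 8 arrays. Of 4 alpha-specific genes 1 was higher and 1 lower (adjusted p = 0.809). The higher one, STE3, was at 0.26 (limma, adjusted p = 0.0301), and 10 of 22 alternatives ended its call in the same direction and 2 turned its direction. Haploid-specific genes had 3 of 11 higher and 6 lower (adjusted p = 0.364). Pheromone response genes had 5 of 9 higher and 3 lower, or 4 lower adjusted over the list alone (adjusted p = 0.416). GPG1, which is named here only because the fixed list holds it, rose by 3.98, and PRM2 rose by 2.45.

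Whole chromosomes were compared because an evolved strain can gain or lose one. Chromosome medians lay between -0.13 for chromosome XIV and 0.19 for chromosome III, over the genes placed on the 16 nuclear chromosomes. None was called by camera, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.914, or 0.97 with an estimated correlation.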

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

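The test by other splits of the samples was set before its result was seen, and all other tests in this part were chosen after the results they concern had been seen. Of the 35 splits of the 8 arrays into 4 and 4, 1 called as many genes as the strains did, the real one with 4847 genes. The highest other split called 0. Every other split puts arrays of both strains in each group, so any difference between the strains' arrays widens the spread within groups. The result shows only that the arrays group by strain, which is also a grouping by slide. This does not separate strain from scan session.

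In 18 of 366 groups of 4 values, 1 array lay far from the other 3, and chance alone gives about 1 in 20 groups. That rate concerns the total and not its spread over arrays, and FD11 replicate 2 held more of these values than any other array. On FD11 replicate 2 they were BDH2 (2.66 against at most 2.40), AQR1 (-5.71), YMR206W (-2.32), GRX1 (2.25), RPS4B (2.31), MAL11 (2.09) and MUP1 (-1.41). On FD11 replicate 1 they were IMD4 (-1.54) and VPH1 (1.43), and on FD11 replicate 4 THI4 (-1.63) and SPS1 (-7.33). In the reference they were RSA4 (-0.13) and DAN1 (-9.46) on replicate 1, CRC1 (-6.25) and SPS19 (-3.86) on replicate 2, CLB1 (0.55) on replicate 3, and CLN1 (-0.13) and the median of the gluconeogenesis and glyoxylate cycle list (-3.96) on replicate 4.

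The first pattern is the rise of general stress genes with the fall of ribosome biogenesis genes, whose medians lie 5.84 apart. A different response of slides or scans to the same input is argued against, for this gap, by the spike-in RNAs. The strain differences of the 7 well above background on all arrays span 0.78, from -0.62 to 0.16. Their median was -0.48, and it was -0.87 for the slide of reference replicate 1 minus that of replicate 3. The spike-ins were therefore not level between strains or slides. An offset shared by both lists does not change the gap. Whether an offset enters single lists with smaller medians was not tested. Cultures, RNA or labelling of another time cannot be told apart from the strain, since 0 slides hold both strains. For a harvest nearer to glucose exhaustion in FD11, the criterion first written, that ADH2 under 0 would exclude it, was met, since ADH2 fell by 0.77 ± 0.23 (SE), and was then replaced by the median of the gluconeogenesis and glyoxylate cycle list, 1.09 against 3.17 for the stress genes. Both criteria were written after their values were seen and neither decides: ADH2 goes against this explanation, but it was the 1 of that list's 21 genes that fell while 19 rose, so it stays open, as does the strain itself, untested.

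The second pattern is the rise of the Pdr1 and Pdr3 targets. A rise of exporters in general is argued against by the 16 exporters outside the regulon, with a median of -0.57, 3 of them higher and 10 lower. The 6 within it had a median of 2.48, and the medians differed (exact permutation test over genes, two-sided, p = 0.00048, genes not being independent replicates). The regulon had been called as higher on these same values, so that p adds no support. Only the values outside it bear on the explanation. Background handling of dim probes is argued against by the authors' values, not background-subtracted, in which the regulon without its 3 members not well above background on every array keeps a median of 1.32. Cultures or labelling of another time cannot be told apart from the strain, as 0 slides hold both. A change in the strain's regulation of these genes is therefore an untested hypothesis.

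The third pattern is in mitochondrially encoded RNAs, including intron-encoded ones, of which 7 of 15 were higher and 5 lower. RNA preparation or labelling that differs between slides may account for part of it: all 15 were higher on the slide of reference replicates 3 and 4, and their median absolute difference between the 2 reference slides was 0.96, against 0.11 over all genes, at percentile 100 of 10000 random lists. The spike-in RNAs were also higher on that slide, with a median of -0.87 for the slide of replicates 1 and 2 minus that of replicates 3 and 4. A shift of about this size was therefore not particular to mitochondrial RNA. One shift of all mitochondrial RNA is argued against by the rarer direction, in which 5 were called: of these, VAR1 (-1.80), BI2 (-3.63) and AI3, not well above background in FD11, differed by more than the reference slides did, while AI1 (-0.89) and AI4 (-0.94) did not. For 8 of the 15 the strain difference over both reference slides was larger than that between the slides, so a strain difference stays open for these. Against each slide alone this did not hold for VAR1 or ATP6. VAR1 was at -1.13 against replicates 1 and 2 (slide difference -1.34), and ATP6 at 0.70 against replicates 3 and 4 (slide difference -0.94).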

How the results depend on the processing

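The comparisons with one reference slide at a time and the ribosomal protein list without RPP1 were added after seeing the data; the other alternatives were planned. Over all settings but single arrays left out, genes higher in FD11 numbered 2324 to 2649 and genes lower 2169 to 2431; at least 2-fold, 820 to 1154 and 809 to 1023. Without single arrays the ranges were 2420 to 2483, 2253 to 2321, 1060 to 1128 and 926 to 958, with 17 to 19 lists called. All 18 list medians kept their direction in every setting. With an estimated correlation 0 lists were called and with fry, which does not compare a list with other genes, 45. An estimated correlation by its construction counts members that vary together as fewer independent ones. That does not account for the whole loss. For the phosphate regulon the estimate was -0.046, under the preset 0.01, yet the unadjusted camera p rose from 0.0351 to 0.0645. By its construction this form of camera also refers its statistic to the few residual degrees of freedom of the arrays. With the preset correlation that number comes from the genes. Both differences act on each p-value given with an estimated correlation, and their shares were not tested. Chromosomes called stayed at 0 in every setting run, including without genes within 30 kb of a chromosome end. Of the 4847 genes called, 4446 kept call and direction against reference replicates 3 and 4 alone, the fewest of any setting, and 4476 with normexp. With quantile normalization 4681 kept them and 4 were called in the opposite direction. The named genes were chosen mostly for large differences. Of 3554 values of 162 named genes under the alternatives, 3516 kept direction and side of the threshold, 14 lost the call and 17 gained one. Among the named genes, direction turned for 2 mating genes. STE3, called at 0.26 (adjusted p = 0.0301), went to -0.071 with quantile normalization (adjusted p = 0.56) and -0.071 with the authors' table (adjusted p = 0.403), and 10 further alternatives ended its call in the same direction. MFA2, not called at 0.061, went to -0.025 with normexp, -0.010 with the authors' table, -0.069 without FD11 replicate 1, -0.012 without FD11 replicate 3 and -0.014 with the reference slide of replicates 3 and 4 alone; the cause was not tested. Without single arrays MFA2 ranged from -0.069 to 0.20. With the slide as a random block, 2524 genes were higher and 2345 lower, which says nothing about strain against scan session, since 0 slides hold both strains and the estimated slide correlation was -0.022. With the replicate block, 2512 genes were higher and 2333 lower. Same-numbered arrays deviated together with correlations across genes of -0.05, 0.28, 0.10 and 0.14, and 2 of 4 FD11 arrays correlated best with their own number, so the numbers are not taken to pair the samples. With 1 probe per gene, choosing the brightest probe was not run. Signal over background limits the 318 genes left out.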

Other observations

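Further genes were picked after their values were seen. They are single members of the copper and zinc list, which was not called (camera, adjusted p = 0.0594, and adjusted p = 0.567 with an estimated correlation). ZRT2, the low-affinity zinc transporter gene, fell by 1.85 ± 0.14 (SE), FET4 fell by 2.40 ± 0.10, ADH4 fell by 2.14 ± 0.08 and ZAP1, the zinc-responsive transcription factor gene, fell by 1.48 ± 0.10. ZRC1, a vacuolar zinc transporter gene, fell by 2.07, and ZPS1 was at 0.05 (limma, adjusted p = 0.664).

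Outside the fixed lists, the permease genes FCY2, for purines and cytosine, and FUI1, for uridine, fell by 3.62 and fell by 3.45. The transcription factor gene PDR1 itself was higher by 0.88 ± 0.08 (SE; limma, adjusted p = 1.13e-06), and PDR3, which is in the regulon's list, by 1.49. Within the hexose transporter list HXT1, a low-affinity glucose transporter gene, fell by 0.92 and HXT3 rose by 0.80.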
